A study of Mus musculus with 18 samples.

How the data were processed

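Messenger RNA of 18 mouse embryo fibroblast (MEF) cultures was measured, each on its own Affymetrix expression array with 22690 probe sets, of which 64 are controls. According to the labels the cells were grown for 2 passages, total RNA was extracted with Trizol, and biotin-labelled cRNA was made from 5 ug of it. The design sets 9 lines with normal chromosomes (controls) against lines with an extra copy of chromosome 1 (1 line), chromosome 13 (4 lines), chromosome 16 (3 lines) or chromosome 19 (1 line). The labels speak of different lines but do not say whether each came from its own embryo, so the p-values measure the spread between these samples.

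The deposited values are log2 expression values of each probe set, which the authors background-corrected, normalized and summarised with GCRMA and the affy package. Versions, settings and whether all arrays were summarised together are not given in the sources used here. The values run from 0.968 to 16.6, and the median of an array lies between 5.11 and 5.91. Arrays give no counting depth, and the number of arrays is 1 limit on the precision.

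A probe set was used when the gene table for this array lists exactly 1 gene for it, which held for 20393 probe sets. Another 691 were listed with several genes and 1606 had no entry. Genes were placed on chromosomes by their Entrez identifier in the RefSeq annotation of assembly GRCm38.p6. Where a gene had several probe sets, the one with the highest mean was kept, which gave 12394 genes, and the 7382 with a mean log2 value of at least 4 over all 18 arrays were tested.

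Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with all 18 arrays in 5 groups that share 1 estimate of the spread (13 residual degrees of freedom). A gene passed at a Benjamini-Hochberg adjusted p under 0.05, two-sided. With a single array, trisomy 1 and trisomy 19 are assumed to vary like the other groups. The contrast of all trisomies gives each of the 9 trisomic arrays the same weight and leaves out genes on chromosomes 1, 13, 16 and 19. The contrast of trisomy 13 minus trisomy 16 leaves out genes on chromosomes 13 and 16. For genes of chromosomes 13 and 16 the log2 fold change was also tested against the log2 of 1.5, which is 0.58.

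The shift of a chromosome is the mean log2 value of its tested genes minus the mean over genes of the other autosomes, computed per array and set to 0 at the control mean. Groups were compared by an exact permutation test, two-sided, which cannot go below 0.2 with 1 array against 9. Gene lists (28, fixed together with the design and the settings before the data were examined) were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and with fry, leaving out genes of the trisomic chromosome. Lists with at least 5 tested genes were used, and the p-values were adjusted over the lists of a comparison. For trisomies 1 and 19 the median of a list is given as a percentile among 10000 random lists of the same size and level.

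The genes named were chosen by a rule fixed in advance. It takes the largest changes past the threshold (up to 8 on the extra chromosome and 6 in each direction elsewhere for trisomies 13 and 16, and 6 on the chromosome and 4 in each direction elsewhere for trisomies 1 and 19). To these it adds up to 4 members of a list in the order of p, and up to 8 known genes of the extra chromosome in the order written. Names outside the rule are marked as chosen after their values were seen.

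RNA quality was read from the 3' and 5' control probe sets of Gapdh and actin. Arrays with a Gapdh 3' minus 5' difference above 3 on the log2 scale are called 3'-biased arrays below. That limit was chosen after the control probe sets were seen. The titles hold a first number that trisomic and control lines share; its meaning is not given in the sources used here. It was used as a replicate block in an alternative fit, as was the replicate number. By replicate number the deviations of trisomy 16 and control replicates 1 to 3 were paired, with correlations of 0.52, 0.41 and 0.58, so a blocked fit over these arrays alone was added.

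The procedure was tested on simulated data, with changes put into 200 of 7382 genes in each of 5 runs. Of genes changed by 1 on the log2 scale it found 41.2% in trisomy 13, 40.0% in trisomy 16, 8.4% in trisomy 1 and 7.6% in trisomy 19, and between 3.03% and 5.96% of all calls were unchanged genes. A chromosome shift of 0.58 was recovered as 0.57 to 0.64 on average. The simulated noise was drawn independently for each gene and array, with no 3' bias and no structure by first number. Shares of false calls in the real arrays can therefore be higher. Alternatives were other filters, probe set summaries and scalings, blocks, other controls, covariates, a fit without the trend, leaving out each array in turn, and fits without the 3'-biased arrays. No array was left out of the values reported first. Figures were drawn with matplotlib.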

Results

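Gene expression was measured in 18 cultures of embryo fibroblasts, connective tissue cells grown from mouse embryos. They comprised 9 control lines with normal chromosomes, 1 line trisomic for chromosome 1, 4 lines trisomic for chromosome 13, 3 lines trisomic for chromosome 16 and 1 line trisomic for chromosome 19, with 1 array per line. Genes of the extracellular matrix, a main product of fibroblasts, had high signals, with a mean of 13.40 on the log2 scale over 27 genes in controls. Markers of liver and erythroid cells had 0 genes above the filter. It was passed by 11 smooth muscle markers, 5 neural, 3 endothelial and 1 skeletal muscle marker. It was also passed by 2 markers each of epithelium, of adipocytes, and of cartilage and bone. The highest means of these lists ran from 6.10 for epithelium to 15.62 for smooth muscle. Of 17 macrophage markers the highest mean over all arrays was 4.95. Single arrays had more: on trisomy 13 replicate 4 the macrophage genes Ctss, Lyz2 and Laptm5, named after their values were seen, were at 9.27, 9.07 and 7.60, and on control replicate 8 at 7.59, 8.73 and 7.72. Correlations between arrays across probe sets ran from 0.915 to 0.997.

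The arrays differed in RNA quality. On 15 arrays, all controls among them, the 3' minus 5' difference of the Gapdh control probe sets lay between -0.20 and 1.41 on the log2 scale. On trisomy 16 replicate 1 it was 6.55, on trisomy 13 replicate 3 it was 6.94 and on trisomy 13 replicate 4 it was 5.57. Actin gave 3.07 to 7.54 on these 3 arrays and 0.32 to 0.98 on the others. Their median signal was 5.11 to 5.29, against 5.62 to 5.91 on the other 15.

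**Figure D1:**
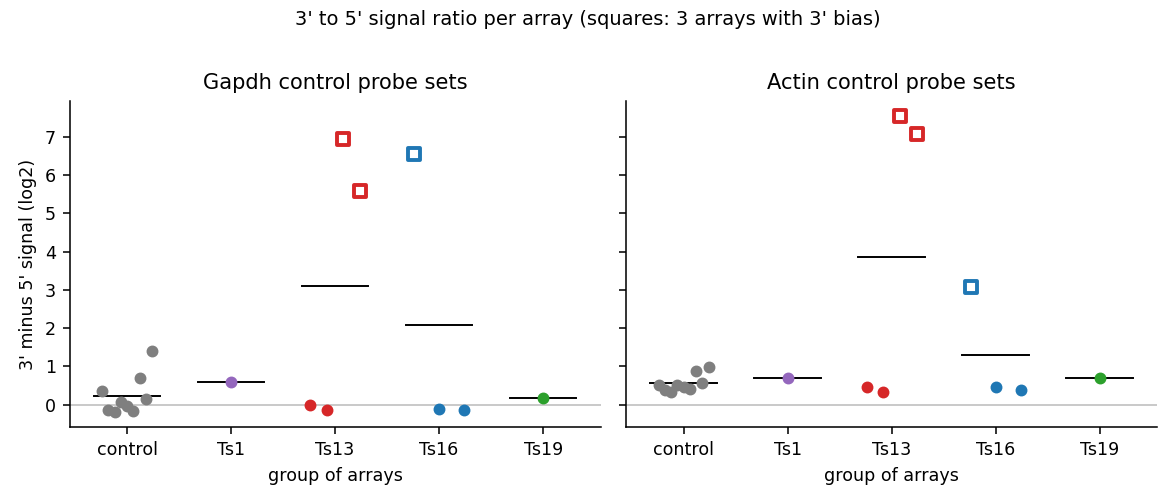
Difference between the 3' and 5' control probe sets of Gapdh (left) and actin (right) on each array, in log2 units, by group; points are arrays, lines are group means and open squares mark the 3 arrays with a 3' bias. The squares lie between 3.07 and 7.54 and all other points at or below 1.41.

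The first question was how far an extra copy raises the expression of the genes on that chromosome. Genes of the extra chromosome were higher in every trisomic culture. Chromosome 13 rose by 0.77 ± 0.18 in trisomy 13 (log2, SD, n = 4; 277 genes; exact permutation p = 0.0028), which is 1.71-fold. Chromosome 16 rose by 0.72 ± 0.05 in trisomy 16 (SD, n = 3; 243 genes; exact permutation p = 0.0091), which is 1.65-fold. Chromosome 1 was higher by 0.72 in trisomy 1 (414 genes) and chromosome 19 by 0.74 in trisomy 19 (260 genes). These last 2 groups hold 1 array each, for which the smallest exact p is 0.2. Over the 4 chromosomes the 9 controls stayed between -0.14 and 0.12. Adjusted over the 4 comparisons, p was 0.011 for chromosome 13 and 0.018 for chromosome 16. On each of the 9 trisomic arrays the extra chromosome had the highest shift of 20 chromosomes. Leaving out the 3'-biased arrays gave a shift of 0.63 for chromosome 13 (n = 2, exact p = 0.036) and 0.70 for chromosome 16 (n = 2, exact p = 0.036). Within blocks of the same first number it was 0.81 for chromosome 13 (exact p = 0.083) and 0.74 for chromosome 16 (exact p = 0.17), each the smallest p such a block allows. Without the filter on the mean level the shifts of chromosomes 1, 13, 16 and 19 were 0.46, 0.50, 0.45 and 0.48.

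**Figure D2:**
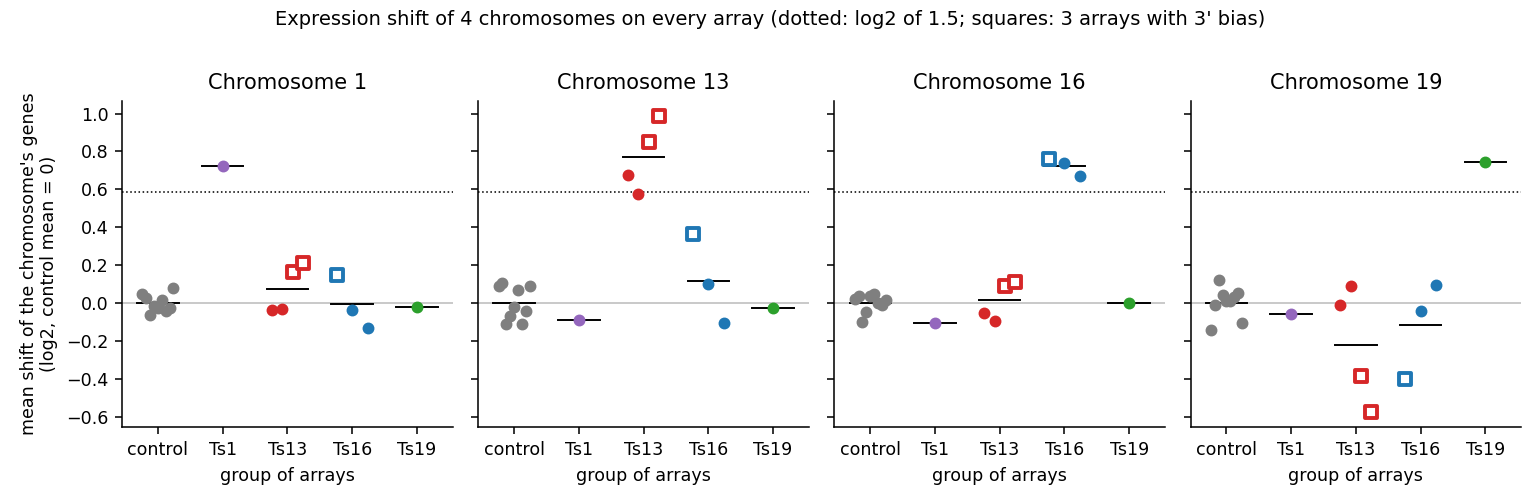
Mean shift of the genes on chromosomes 1, 13, 16 and 19 on each array, in log2 units with the control mean at 0, by group (Ts, trisomy); points are arrays, lines are group means, open squares are the 3 arrays with a 3' bias and the dotted line is the log2 of 1.5. Each trisomic array lies at 0.578 or above for its own chromosome, and the controls lie between -0.14 and 0.12. The lowest, trisomy 13 replicate 2, is just under the dotted line.

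The rise covered most genes of each extra chromosome. In trisomy 13, 249 of 277 genes of chromosome 13 were above the control mean (89.9%), with a median of 0.64. In trisomy 16, 215 of 243 genes of chromosome 16 were above it (88.5%), with a median of 0.61. The corresponding medians were 0.70 for chromosome 1 (90.6% above) and 0.58 for chromosome 19 (96.9% above), whereas genes elsewhere had medians between -0.10 and 0.03. Against a change of exactly 1.5-fold, 3 genes of chromosome 13 rose further. These were Akr1c14, an aldo-keto reductase (log2 fold change 4.05), Glrx, the glutaredoxin that reduces protein disulfides with glutathione (1.95), and Gpr137b (1.92). The count was 0 without the 3'-biased arrays, without trisomy 13 replicate 3 and without trisomy 13 replicate 4. It was 8 without trisomy 13 replicate 1, 5 without replicate 2 and 6 without trisomy 16 replicate 1. On chromosome 16 limma found 0 genes away from 1.5-fold, with 33 at an unadjusted p under 0.05 where 12.2 would be expected, and 1 gene each without trisomy 16 replicate 3 and without control replicate 9.

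**Figure D3:**
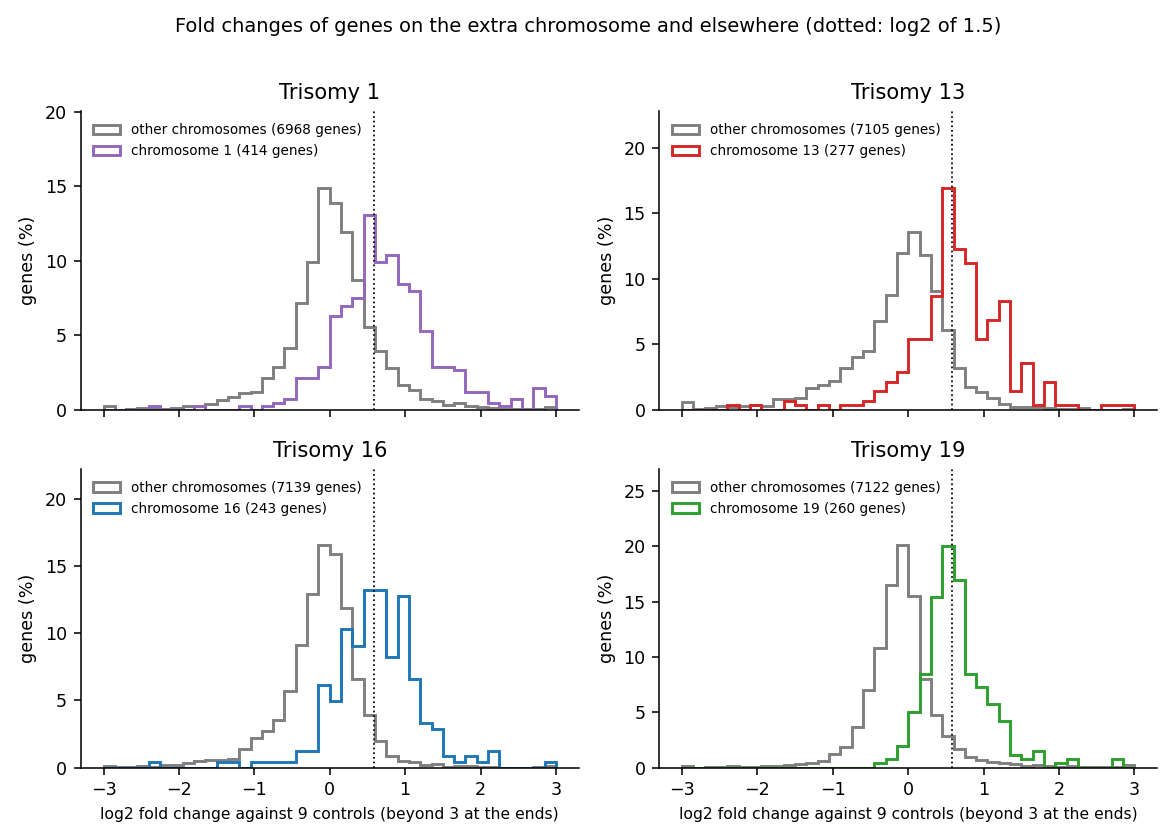
Share of genes (percent) by log2 fold change against the 9 controls, for genes on the extra chromosome (coloured) and on all others (grey), in each trisomy; the dotted line is the log2 of 1.5. The coloured distributions have medians between 0.58 and 0.70 and the grey ones between -0.10 and 0.03.

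Trisomy 13 was compared with the controls gene by gene. On chromosome 13 itself, 40 genes rose and 0 fell. Among the rises past the threshold were Akr1c14 (4.05 ± 0.60, log2 fold change ± SE, n = 4 against 9, adjusted p = 0.0026), Glrx (1.95 ± 0.30), Gpr137b (1.92 ± 0.26) and Nqo2, a quinone reductase (1.65 ± 0.37). Pfkp, a phosphofructokinase of glycolysis, rose by 1.63 ± 0.27, Epdr1 by 1.53 ± 0.27, Caml by 1.33 ± 0.24 and Serf1 by 1.30 ± 0.26 (0.82 on unbiased arrays alone). All 8 were above the control mean in 4 of 4 arrays. For Akr1c14 the controls ran from 2.55 to 5.10, most of them below the filter level of 4, so the size of its rise is not well measured. Of 20 measured genes written down beforehand as known genes of chromosome 13, 19 were above the control mean and 8 rose when adjusted over the list alone, against 1 over all genes. The latter was Rasa1, a Ras GTPase-activating protein (1.09 ± 0.18, adjusted p = 0.0058). Others on that list had Pik3r1 at 1.07, Ptch1 at 1.08, Msh3 at 0.80, Cdk7 at 0.54, Map3k1 at 0.51, Ccnh at 0.30 and Vcan at 0.10, with adjusted p between 0.14 and 0.86. On unbiased arrays alone Ptch1 was at 0.30, Msh3 at 0.01, Cdk7 at 0.90, Map3k1 at 0.19 and Vcan at -0.29, and within blocks of the first number Pik3r1 was at 0.34.

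Outside chromosome 13, 41 genes rose and 49 fell in trisomy 13. Mdk, which encodes the heparin-binding growth factor midkine, fell by 4.86 ± 0.42 (SE, n = 4 against 9, adjusted p = 1.9e-05), from 9.05 ± 0.71 in controls to 4.19 ± 0.92 (SD). Dlk1, an imprinted gene for a Notch-like membrane protein, fell by 4.21 ± 0.58 (adjusted p = 0.0017). Ncapd2, a condensin subunit, fell by 3.73, Aurka, a mitotic kinase, by 3.59, Sema5a, a semaphorin, by 3.01, and Tnnt2, cardiac troponin T, by 2.94. Eno3, the muscle isoform of the glycolytic enzyme enolase, rose by 2.28 ± 0.28 (adjusted p = 0.00084). Further rises were Stk26, a protein kinase (4.25), Ampd3, an AMP deaminase (3.07), S100a1, a calcium-binding protein (2.39), Itgbl1 (2.38) and Spint2, a serine protease inhibitor (2.29). Relative to the mean of all 9 controls, each of these 12 genes moved the same way in 4 of 4 arrays. Some values were below the filter level of 4, where signal and background are hard to separate, so these sizes are not well measured and give no order among the genes. This holds for trisomy 13 arrays with Mdk (replicates 1 and 4), Sema5a (replicates 1, 3 and 4) and Dlk1, Ncapd2 and Aurka (the 3'-biased replicates 3 and 4), and for controls with Stk26 and Spint2. Of the 4 arrays 2 are 3'-biased, with Gapdh differences of 6.94 and 5.57, and on the other 2 alone Ncapd2 was at -1.78 and Aurka at -0.94, neither past the threshold. Tnnt2 was at -1.81 within blocks of the first number (adjusted p = 0.23), and at 6.44 in replicate 3 it lay between the controls of its own number, 5.70 and 7.09.

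On the unbiased arrays alone 14 genes passed in trisomy 13 (8 up on chromosome 13, and 3 up and 3 down elsewhere), of which 10 were among the 130. Those outside chromosome 13 that passed both ways were Mdk (-5.14 without these arrays), Eno3 (2.27), and 3 named here after their values were seen: Slc7a3, a transporter of cationic amino acids (-2.53), Lgals3, the galactose-binding lectin galectin-3 (1.10), and Cystm1 (1.62). The count of 130 became 6 with the first number as a block and 9 with the replicate number as a block. Leaving out trisomy 13 replicate 1, 2, 3 or 4 gave 310, 734, 41 and 26 genes, and leaving out trisomy 16 replicate 1 gave 209. Without control replicate 3, 5, 6, 7 or 8 the counts were 80, 77, 78, 77 and 63.

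Cell division genes were lower in trisomy 13. The 29 mitosis genes fell together (mean log2 fold change -1.06, camera adjusted p = 5.2e-09), all 29 being below the control mean. With an estimated correlation the adjusted p was 0.53. Over all genes 2 fell (Aurka, and Bub1b of the spindle checkpoint by 1.61), and 15 fell when adjusted over the list alone. Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, was at -2.17 (adjusted p = 0.064) and Cenpe, a kinetochore motor, at -2.27 (adjusted p = 0.074). The 29 DNA replication genes also fell (mean -0.73, adjusted p = 2.0e-07; adjusted p = 0.53 with an estimated correlation). Of these, 3 fell over all genes: Mcm5 by 2.23 and Mcm3 by 1.03, subunits of the replicative helicase, and Lig1, which joins Okazaki fragments, by 1.03. Adjusted over the list alone, 10 fell, and Pcna, the sliding clamp, was at -1.30 (adjusted p = 0.064). As means per array, mitosis genes were between -1.46 and -0.83 in the 4 trisomy 13 arrays and between -0.59 and 0.95 in the controls (exact permutation p = 0.0028, adjusted 0.019). Replication genes gave the same p values. With fry neither list passed, the adjusted p being 0.088 for each, and 0.29 for each on unbiased arrays alone. The means on unbiased arrays alone were -0.97 and -0.77 (exact p = 0.036 each, adjusted 0.15), and 0 single genes of either list passed even over the list alone. The changes of Aurka (-0.94), Bub1b (-0.95), Ube2c (-0.79), Mcm5 (-1.07) and Pcna (-0.40) were then much smaller than with all 4 arrays, whereas those of Cenpe (-1.80), Mcm3 (-0.80) and Lig1 (-1.12) moved less. Against controls with the same first number, that is within blocks, the differences were -0.77 and -0.60 (exact permutation p = 0.083, the smallest possible).

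**Figure D4:**
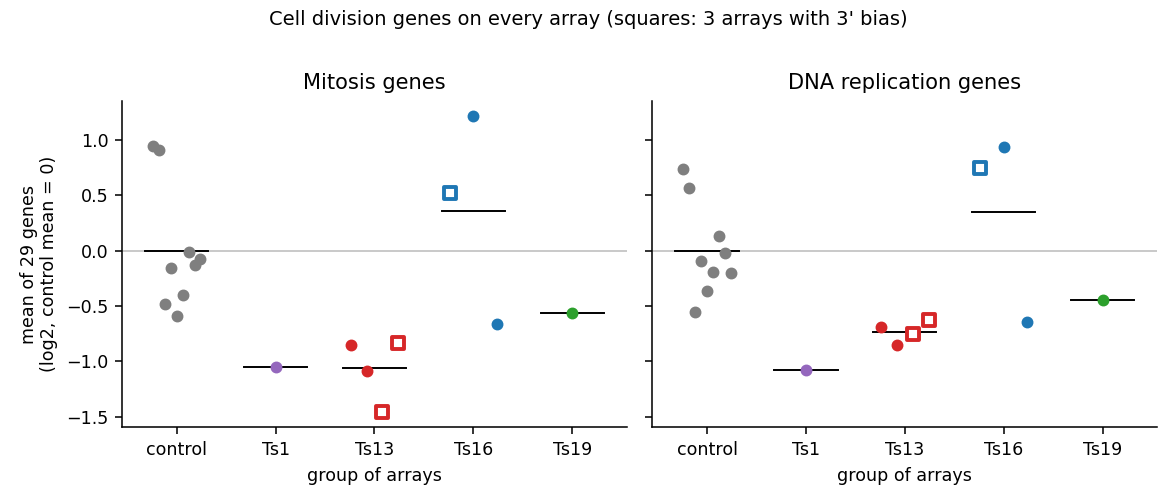
Mean log2 value of 29 mitosis genes (left) and 29 DNA replication genes (right) off chromosome 13 on each array, with the control mean at 0, by group (Ts, trisomy); points are arrays, lines are group means and open squares are the 3 arrays with a 3' bias. The trisomy 13 arrays lie between -1.46 and -0.83 for mitosis and below the lowest control, -0.59; trisomy 16 spans from -0.67 to 1.22.

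In trisomy 13 a further 6 of the 20 lists tested passed with camera, and 0 of the 20 lists passed with an estimated correlation, where the lowest adjusted p was 0.53. Imprinted genes fell (mean -0.96, 12 genes, adjusted p = 0.0020; 0.53 with an estimated correlation). Dlk1 fell over all genes and 5 genes fell adjusted over the list alone. Mest was at -2.41 (-2.54 on unbiased arrays alone), Igf2, a fetal growth factor, at -1.67 (-0.48) and Grb10 at -0.31 (-0.24). Cytosolic ribosome genes fell by a mean of 0.18 with 28 of 34 genes below the control mean (adjusted p = 0.00091; 0.53 estimated), with 0 past the test singly; Rplp0 was at -0.85 and Rps19 at -0.40, but at -0.024 and -0.13 on unbiased arrays alone. Cholesterol synthesis genes (mean -0.49, adjusted p = 0.027; 0.59 estimated) included Dhcr7 at -1.18 (-1.47 on unbiased arrays alone) and Fasn at -1.35 (-0.093). The extracellular matrix list (-0.62, adjusted p = 0.036; 0.59 estimated) held both falls, such as Timp3, an inhibitor of matrix proteases (-1.38; -0.88 on unbiased arrays alone), and a rise of Lox, a collagen cross-linker (0.34); Fbln1 was at -3.47 (adjusted p = 0.063). Interferon response genes rose (0.37, 11 genes, adjusted p = 0.033; 0.53 estimated), with Gbp2 at 1.34 and Ifit2 at 0.94; within blocks of the first number the list mean was 0.27 and Gbp2 was at 0.52, and on unbiased arrays alone Ifit2 was at 0.58. Serum response genes rose (0.28, 16 genes, adjusted p = 0.033; 0.59 estimated), with Dusp1 at 0.90 and Myc at 0.77 (0.39 within blocks). The means without the 3'-biased arrays were -0.76 for imprinted, -0.12 for ribosome, -0.15 for cholesterol, -0.38 for matrix, 0.50 for interferon and 0.43 for serum response genes, and cholesterol and matrix genes then had adjusted p of 0.43 and 0.40. Inside blocks of the first number the serum response mean was -0.07. The other 12 lists had adjusted p between 0.12 and 0.96 and these means: p53 targets 0.04, senescence and secreted factors 0.49, heat shock -0.13, unfolded protein response -0.20, proteasome -0.30, glycolysis and hypoxia -0.09, oxidative phosphorylation -0.20, Nrf2 0.03, lysosome -0.16, Hox genes 0.09, smooth muscle markers -0.22 and neural markers 0.07. On unbiased arrays alone 2 of these 12 passed with camera: Nrf2 genes rose (0.52, 15 of 17 genes above the control mean, adjusted p = 7.0e-05; 0.36 estimated) and lysosome genes rose (0.47, 18 of 18, adjusted p = 7.2e-07; 0.43 estimated). With all arrays the lysosome mean was negative but the median was 0.17, with 11 of 18 genes above the control mean.

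In trisomy 16, 3 genes rose, all on chromosome 16, and 0 fell. Vps26c, a subunit of an endosomal sorting complex, rose by 1.26 ± 0.17 (log2, SE, n = 3 against 9, adjusted p = 0.0052). Atg3, which conjugates the lipid to autophagy proteins of the Atg8 family, rose by 0.94 ± 0.13 (adjusted p = 0.0052), and Pdia5, a protein disulfide isomerase, by 0.92 ± 0.15 (adjusted p = 0.037). All 3 were above every control in 3 of 3 arrays. Adjusted over the 243 genes of chromosome 16, 96 rose and 0 fell. Of 20 known genes of chromosome 16, 17 were above the control mean and 9 rose when adjusted over the list alone, against 0 over all genes. Dyrk1a, a kinase gene also studied in Down syndrome, was at 0.76 and the interferon receptor gene Ifnar2 at 0.80. Others depended on the arrays and controls used, and none passed. In the pairs by replicate number App and Sod1 were above the paired control every time, whereas Ets2, Runx1, Ifnar1 and Ifngr2 were not. App was at 0.05 (0.11 on unbiased arrays alone, 0.40 within blocks of the first number), Sod1 at 0.30 (-0.15, 0.46) and Ets2 at -0.38 (-0.74, 0.17). Runx1 was at -0.96 (0.12, -0.69), Ifnar1 at 0.16 (0.41, 0.18) and Ifngr2 at 0.02 (1.40, -0.11), where the 3'-biased replicate 1 had Runx1 at 5.94 and Ifngr2 at 5.31 against control means of 9.05 and 8.05. Off chromosome 16 limma found 0 genes; on all chromosomes 516 had an unadjusted p under 0.05.

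Replicate 1 of trisomy 16 is 3'-biased (Gapdh difference 6.55). Without it, as without all 3'-biased arrays, 0 genes passed in trisomy 16 (9.02% of the 7382 genes had an unadjusted p under 0.05 in the latter fit), and 63 rose when adjusted over chromosome 16 alone. The count was also 0 with either replicate block, 7 without trisomy 16 replicate 3, 7 without control replicate 1, 8 without control replicate 9 and 6 without trisomy 13 replicate 4.

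Of 19 lists, 4 passed with camera in trisomy 16 and 0 with an estimated correlation (adjusted p = 0.88 for each of the 4) or with fry. Mitosis genes rose (mean 0.36, adjusted p = 8.4e-05) with Aurkb at 0.77 and Ccnb2 at 0.63, and DNA replication genes rose (0.23, adjusted p = 0.014) with Ccne1 at 0.75 and Slbp at 0.57. Lysosome genes fell (-0.43, adjusted p = 0.018) with the channel gene Mcoln1 at -0.99 and the protease gene Ctsd at -1.07, and serum response genes fell (-0.51, adjusted p = 0.018) with Ier3 at -1.01 and Egr1 at -1.11. No gene of these lists passed over all genes. Of the 16 serum response genes 3 were above the control mean. Klf4 was among them, at 12.15 to 12.80 against 11.26 to 12.46 in the controls. The 3 arrays were spread widely, with mitosis means of 0.52 on the 3'-biased replicate 1, 1.22 on replicate 2 and -0.67 on replicate 3. Without replicate 2 the mitosis mean was -0.07 and the replication mean -0.07, and within blocks of the first number they were -0.10 and -0.02. Serum response and lysosome genes were at -0.17 (exact p = 0.33) and -0.20 (exact p = 0.50) within these blocks. Within them Mcoln1 was at -0.47, Ctsd at -0.76, Egr1 at 0.09, Ier3 at -0.95, Aurkb at 0.27, Ccnb2 at 0.13, Ccne1 at 0.32 and Slbp at 0.30. On unbiased arrays alone the means were 0.28 for mitosis (adjusted p = 0.00016), 0.04 for replication (0.068), -0.17 for lysosome (0.79) and -0.46 for serum response genes (0.10), so that only mitosis kept its call. Another 4 lists passed there, all higher: matrix (0.30, adjusted p = 0.00016), cholesterol (0.24, 0.00056), Hox (0.32, 0.016) and smooth muscle marker genes (0.13, 0.043). With an estimated correlation each of these 5 had an adjusted p of 0.95. Of the genes named, Aurkb was then at 0.39, Ccnb2 at 0.29, Ccne1 at 0.44, Slbp at 0.29, Mcoln1 at -0.75 and Ctsd at -0.12.

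For trisomy 1, a single array, 3 genes passed the threshold. Their errors and p-values borrow the spread of the other groups and do not measure variation between trisomy 1 lines. Rgs5, a regulator of G-protein signalling on chromosome 1 found in pericytes, rose by 4.45 ± 0.66 (log2, SE, adjusted p = 0.011). Sncg, gamma-synuclein, rose by 2.51 ± 0.37 (adjusted p = 0.011) from a flat control level of 3.71 to 3.84, below the filter level of 4; if that level is background, the fold change is a lower bound. Mxd3, a Max-binding transcription factor, fell by 3.11 ± 0.36 (adjusted p = 0.0013). Rgs5 was also above the others in control replicate 9, at 5.67 against a control mean of 4.12, itself close to the filter level. That control has the first number of the trisomy 1 line, and against it, within the block, Rgs5 was at 2.90. Mitosis genes had a median of -1.06 and replication genes one of -1.23, each at percentile 0 of the random lists, with 27 of 27 and 25 of 26 genes below the controls. Lysosome genes had a median of 0.63 (percentile 100), smooth muscle markers 0.53 (percentile 100) and p53 targets 0.46 (percentile 99.9). Of known genes of chromosome 1, Tgfb2 was at 1.32, Ptgs2 at 1.22, Igfbp2 at 1.19, Ncl at 0.54, Igfbp5 at 0.36, Fn1 at 0.28, Col5a2 at 0.26 and Col3a1 at 0.06. Against control 9 alone, within the block, these were at 1.72, 2.24, 0.85, 0.71, -0.24, 0.30, 0.13 and -0.13 in the same order, so Igfbp5 and Col3a1 turned direction. Of the 20 measured, 18 were above the control mean and 3 rose when adjusted over the list alone, against 0 over all genes. The count of 3 became 0 with either replicate block, 14 without control replicate 9, 45 without a filter and 5 without the 3'-biased arrays, none of which is from trisomy 1.

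For trisomy 19 limma found 0 genes past the threshold, with 145 at an unadjusted p under 0.05 and 40 past the threshold without a filter. On chromosome 19, 252 of 260 genes were above the control mean. Of known genes there, 18 of 18 were above it, with 1 past the test adjusted over the list alone and 0 over all genes. Fas, a death receptor, was at 1.67, Malat1 at 1.23, Ahnak at 0.68, Scd1 at 0.48, Vegfb at 0.46, Fth1, the ferritin heavy chain, at 0.43, Acta2 at 0.20 and Scd2 at 0.17. Against control 8 alone, which has its first number, that is within the block, these were at 1.86, 1.30, 0.39, 0.39, 0.84, 0.37, 0.03 and 0.07 in the same order. Senescence and secreted factor genes had a median of 0.90 and serum response genes 0.66, both at percentile 100, while mitosis genes had -0.58 and replication genes -0.49, both at percentile 0. With 1 array these percentiles describe that culture and not its spread between cultures.

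Changes shared by the trisomies were sought among 6188 genes off the 4 chromosomes. Eno3 rose by 1.43 ± 0.22 and Sncg by 1.07 ± 0.16, while Mdk fell by 2.15 ± 0.33 and Slc7a3 by 1.46 ± 0.23 (log2, SE, n = 9 against 9, adjusted p = 0.013 each). Eno3, Sncg and Slc7a3 moved that way in 8 of 9 trisomic arrays and Mdk in 7 of 9. Trisomy 13 holds 4 of the 9 arrays and weighs most, so these changes were not shared evenly. Mdk was at 3.50 to 5.45 in trisomy 13 and 7.75 to 8.45 in trisomy 16. It was at 10.52 in trisomy 19 and 10.75 in trisomy 1, against 7.70 to 10.14 in the controls. Slc7a3 was at 6.69 to 7.94 in trisomy 13 and 8.08 to 9.49 in trisomy 16, against 8.82 to 10.12 in the controls. For Sncg, with controls at 3.71 to 3.84, the fold change is again a lower bound if that level is background. Mitosis genes fell by a mean of 0.56 (adjusted p = 5.7e-06; 0.52 with an estimated correlation) and replication genes by 0.44 (adjusted p = 2.2e-05; 0.52 estimated), with 26 of 26 and 20 of 21 below the controls. Among them Plk1, a mitotic kinase, was at -1.86, Cenpe at -1.37, Mcm5 at -1.19 and Mcm2 at -0.88, and 0 genes passed singly; on unbiased arrays alone these were at -0.355, -0.89, -0.60 and -0.37. Adjusted over the list alone, 0 mitosis and 2 replication genes fell. Ribosome genes fell by 0.09 (adjusted p = 0.038; 0.52 estimated), but on unbiased arrays alone the mean was -0.056 and the call was lost (adjusted p = 0.28). Rplp0 was at -0.41, but at 0.0075 on unbiased arrays alone. By exact permutation of means per array, 0 lists passed, and mitosis genes had p = 0.12 (adjusted 0.37) over all splits and p = 0.040 (adjusted 0.28) within blocks of the first number.

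The 3'-biased arrays are 3 of these 9 trisomic arrays. Without them the count was 2 genes, Slc7a3 (-1.50) among them, and mitosis and replication means were -0.51 and -0.50. With camera 10 lists then passed, 7 higher and 3 lower, of which mitosis and replication were shared with the 3 lists of all arrays. Among the others were lysosome (0.20, adjusted p = 1.9e-05), Nrf2 (0.26, 0.00044) and oxidative phosphorylation genes (-0.11, 0.022), and with an estimated correlation 0 passed (adjusted p = 0.46 for each of these 5). The count of 4 was 0 with either replicate block, 0 without trisomy 13 replicate 1, 2 or 4, 2 without its replicate 3 and 7 without control replicate 1.

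Trisomy 13 and trisomy 16 differed from each other in 63 of 6862 genes off both chromosomes, 37 higher and 26 lower in trisomy 13. Of 19 lists, 8 differed with camera and 0 with an estimated correlation, where the lowest adjusted p was 0.33. Relative to trisomy 16, trisomy 13 was lower in mitosis (-1.42), replication (-0.95), imprinted (-0.67), matrix (-0.57), cholesterol (-0.50) and ribosome genes (-0.13), and higher in serum response (0.79) and lysosome genes (0.30). Within blocks of the first number these were, in the same order, -0.67, -0.57, -1.19, -0.95, -0.75 and -0.16, then 0.10 and -0.08, and the last 2 lost their calls (adjusted p = 0.18 and 0.23). On unbiased arrays alone they were -1.25, -0.79, -0.64, -0.65, -0.39 and -0.047, then 0.90 and 0.65, all past camera. The list members past the test over all genes, seen before they were named, were Dlk1 (-3.67), Timp3 (-2.04) and Ier3 (1.47). Without the 3'-biased arrays 3 genes passed, chosen here after their values were seen: Mdk (-4.19), Cavin4 (3.57) and Stmn2, a neuronal tubulin-binding protein (6.93), with sizes not well measured since each had a value or a group mean near or below the filter level of 4. The count of 63 became 1 and 0 with the replicate blocks. Without trisomy 16 replicates 1, 2 or 3 it was 160, 8 and 27, without trisomy 13 replicates 1 to 4 it was 22, 99, 37 and 8, and without control replicates 6 or 8 it was 37 and 40. Across these genes, which are not independent replicates, the fold changes of the trisomies against their own controls correlated with r = 0.27 (Spearman 0.29). Without the 3'-biased arrays r was -0.29, and without trisomy 16 replicate 1 it was -0.39, so its sign rested on these arrays.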

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

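The tests of RNA degradation, of a batch and of an extra chromosome of any kind below were chosen after the results were seen; the counts of other splits of the arrays were planned before they were run. Control probe sets, which the comparisons do not use, gave a signal on 3 arrays that no control array had. The 3' minus 5' difference of Gapdh was 6.55 on trisomy 16 replicate 1, 6.94 on trisomy 13 replicate 3 and 5.57 on trisomy 13 replicate 4, against -0.20 to 1.41 on the other 15 arrays. A difference of this kind arises when RNA is degraded or incompletely copied, and these data do not separate the 2.

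Does this 3' bias account for the changes outside chromosome 13 in trisomy 13? When genes were called from the 2 biased trisomy 13 arrays alone, 1165 passed outside chromosome 13, and their median change in the called direction was 0.80 on the biased trisomy 16 array but 0.13 and -0.15 on the unbiased trisomy 13 arrays. Those calls may therefore come largely from RNA quality. For the changes of all 4 arrays the answer stays open, since the 2 unbiased arrays disagree. Genes called without replicate 1 moved on it by 0.353 of their change on the biased arrays. Genes called without replicate 2 moved on that one by -0.0230, and the mean share was 0.160. The biased arrays took part in these calls and the left-out array did not, which by itself lowers the shares. On the biased trisomy 16 array the medians of these genes in the called direction were 0.052 and 0.13. On the biased trisomy 13 arrays they were 1.68 and 1.77. On the other unbiased trisomy 13 array, which also took part in the call, they were 0.73 and 0.37. Unlike the 1165 genes, these genes moved little with the bias of trisomy 16, but that is 1 array and cannot decide the question. In these fits trisomy 13 and trisomy 16 each mixed biased and unbiased arrays. A gene that follows the bias then has a wide spread and is harder to call. The other splits of the arrays make chance unlikely for the count of 130 genes, with 2 as the highest of 99 other splits. Of the 130, however, 40 lie on the extra chromosome, and the 90 off it were not tested apart. A quality difference between groups would pass that test too.

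The lower expression of mitosis and replication genes in trisomy 13 is the second pattern weighed. Degradation as its whole cause is argued against by the unbiased arrays, the higher of which had a mitosis mean of -0.85, below the lowest control at -0.59. A batch shared by arrays with the same first number stays open: within numbers the difference was -0.77, in the same direction in 4 of 4 arrays, but the exact p of 0.083 is the smallest possible, and controls 1 and 3, which share a number, differ by 1.43. An effect of any extra chromosome could also contribute, since 7 of 9 trisomic arrays lay below the controls of their own number. The 4 trisomy 13 arrays, in which the pattern was found, are among the 7 and give no separate support. Of the rest, trisomy 16 replicate 3, trisomy 1 and trisomy 19 lay below, and trisomy 16 replicates 1 and 2 lay above. The count of 7 depends on the control used. Trisomy 16 replicate 1, at 0.52 for mitosis, lies above the mean of controls 1 and 3. It lies below control 1 alone (0.95), with which it pairs by replicate number. For replication it is at 0.75 against 0.74, and replicate 2 lies above its control for both lists, so this explanation stays open. For the 8 lists past the threshold in trisomy 13 chance cannot be excluded, as 10 of 100 splits gave as many and the highest other split gave 11.

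The shift of chromosome 13 was larger on the biased trisomy 13 arrays than on the others, by 0.29. On the biased trisomy 16 array, which has no extra chromosome 13, it was 0.36, outside the controls at -0.11 to 0.11. A drift of chromosome means with RNA quality may thus explain the difference, and the value from the unbiased arrays alone was 0.63. No biological explanation of this difference was tested.

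Trisomy 13 and trisomy 16 differed by a test of the difference itself in 63 genes and, with camera at the preset correlation, in 8 of 19 lists. With an estimated correlation 0 of the 19 lists differed (lowest adjusted p = 0.33), and with fry 0. The list differences were -1.42 for mitosis, -0.95 for DNA replication, -0.13 for ribosome, -0.50 for cholesterol synthesis, 0.30 for lysosome, -0.57 for extracellular matrix, 0.79 for serum response and -0.67 for imprinted genes. Within blocks of the first number they were -0.67, -0.57, -0.16, -0.75, -0.08, -0.95, 0.10 and -1.19 in that order, so the lysosome mean turned negative and both lysosome and serum response lost their calls (adjusted p = 0.23 and 0.18). On unbiased arrays alone they were -1.25, -0.79, -0.047, -0.39, 0.65, -0.65, 0.90 and -0.64. Chance was not excluded by the splits. At least 63 genes came from 4 of the 35 splits of the 7 arrays, and 8 lists from 2 of the 35, the highest other split also giving 8. The highest other split for genes, with 2629, set the 3'-biased against the unbiased arrays. Splits with 1502 and 1103 genes also had all 3'-biased arrays on the same side. These splits carry RNA quality, so their number cannot tell how often chance gives 63 genes. For the 3 genes of trisomy 16, 8 of 100 splits gave as many (highest other 333), and for its 4 lists 75 of 100 (highest other 13). For all trisomies, 5 of 100 splits gave 4 genes or more (highest other 291) and 90 of 100 gave 3 lists or more (highest other 10), so chance cannot be excluded in any of these. Splits that call 333 and 291 genes also point to a structure of the samples other than the groups, and which structure this is was not tested.

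Single samples far from the rest of their group were control replicate 9 for Rgs5 (5.67), trisomy 13 replicate 2 for Sema5a (4.71) and trisomy 13 replicate 2 for Pdia5 (11.70). These are 3 of 119 groups tested, and chance alone marks about 1 in 20 groups, here 5.95.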

How the results depend on the processing

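The fits without the 3'-biased arrays, with the Gapdh difference as a covariate, with the block over trisomy 16 and control replicates 1 to 3, with fry and with exact permutation of list means were chosen after the data were seen; the other alternatives were planned. The shifts of the 4 chromosomes kept their sign under every alternative run, between 0.45 and 0.89, and without 1 array at a time they lay at 0.71 to 0.73 (chromosome 1), 0.70 to 0.84 (chromosome 13), 0.70 to 0.75 (chromosome 16) and 0.73 to 0.76 (chromosome 19). Named genes past the threshold gave 1205 values under alternatives, of which 867 stayed past it, 338 did not and 0 reversed. Called lists gave 605 values, of which 470 stayed past the threshold, 126 did not and 9 had a mean of the other sign. Most values in both totals come from leaving out 1 array at a time, so the totals hide differences between alternatives. Of 37 gene calls, 1 stayed with the first number as a block and 4 with the replicate number. Without the 3'-biased arrays 9 of 37 stayed, and with centring on the median 37 of 37. Of the list calls 0 stayed with an estimated correlation, 2 with fry and 17 without the 3'-biased arrays. Signal near background, the number of arrays and RNA quality can each limit these results, and their shares were not tested. Weights per array did not converge and were not run. Except where said otherwise the cause was not tested.

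Without a filter, which adds genes near background, the counts were 45 for trisomy 1, 8 for trisomy 16, 40 for trisomy 19 and 11 for all trisomies, and the shifts of chromosomes 1, 13, 16 and 19 were 0.46, 0.50, 0.45 and 0.48. Trisomy 1 gave 1 gene at a mean log2 of at least 6, 1 with the mean of all probe sets, 1 after a further quantile normalization and 6 without the trend. All trisomies gave 1 gene after quantile normalization and 0 in a 2-group fit. Centring on the median of other chromosomes gave 221 genes in trisomy 13, 14 in trisomy 16 and 8 in all trisomies, and moved the median of all genes by 0.13 in trisomy 19. The median over genes gave 0.65 for chromosome 1, and with the measured median as the reference 5 genes of chromosome 13 lay away from it.

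With the first number as a replicate block, which leaves fewer degrees of freedom, the counts were 0 for trisomy 1, 6 for trisomy 13, 0 for trisomy 16, 0 for all trisomies and 1 for trisomy 13 minus trisomy 16, with 0 chromosome 13 genes away from 1.5-fold. The shifts were 0.64 for chromosome 1, 0.81 for chromosome 13 (exact p = 0.083) and 0.74 for chromosome 16 (exact p = 0.17). In this block, and by permutation within the number, the mean of the serum response list of trisomy 13 changed sign to -0.070 and those of the mitosis and replication lists of trisomy 16 to -0.10 and -0.023; in the block that of the lysosome list of trisomy 13 minus trisomy 16 changed sign to -0.079. With the replicate number as a block the counts were 0, 9, 0, 0 and 0, and the shifts 0.67, 0.77 (exact p = 0.13), 0.74 (exact p = 0.25) and 0.89; with this block over trisomy 16 and control replicates 1 to 3 alone they were 0 genes and 0.74 (exact p = 0.25). Controls with the same first number alone gave 1 gene for trisomy 1, 25 for trisomy 13, 0 for trisomy 16 and 0 for the difference, with shifts of 0.64 for chromosome 1 and 0.74 for chromosome 16 (exact p = 0.10). As a random block the number gave 106 genes for the difference, and the arrays of that comparison alone gave 2.

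Without the 3'-biased arrays the counts were 5 for trisomy 1, 14 for trisomy 13, 0 for trisomy 16, 2 for all trisomies and 3 for the difference, with 10 lists for all trisomies (7 up, 3 down), 0 chromosome 13 genes away from 1.5-fold and a correlation of -0.29. Adding the random block gave 6 for trisomy 1 and 43 for trisomy 13. With the Gapdh covariate the counts were 12, 46, 14 for trisomies 1, 13 and 16 and 195 for the difference, with 10 lists for all trisomies (7 up, 3 down) and a correlation of -0.21. With an estimated correlation the lists past the threshold were 0 in each of the 4 comparisons. With fry they were 2 for trisomy 13, the ribosome and imprinted lists, and 0 for the other 3. With genes of the trisomic chromosome kept they were 5 for trisomy 13. By permutation they were 4 for trisomy 13, 0 for trisomy 16 and 0 for all trisomies, and within the number 0 for each of these 3.

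Leaving out 1 array at a time gave 3 to 14 genes for trisomy 1 (highest without control 9) and 0 to 0 for trisomy 19. Trisomy 13 gave 26 (without its replicate 4) to 734 (without its replicate 2), with 310 without replicate 1, 41 without replicate 3, 209 without trisomy 16 replicate 1, and 80, 77, 78, 77 and 63 without controls 3, 5, 6, 7 and 8. Trisomy 16 gave 0 (without its replicate 1) to 8 (without control 9), with 7 without its replicate 3, 7 without control 1 and 6 without trisomy 13 replicate 4. All trisomies gave 0 (without trisomy 13 replicate 1, 2 or 4) to 7 (without control 1), and 2 without trisomy 13 replicate 3. The difference gave 8 (without trisomy 16 replicate 2 or trisomy 13 replicate 4) to 160 (without trisomy 16 replicate 1), with 27 without trisomy 16 replicate 3, 22, 99 and 37 without trisomy 13 replicates 1, 2 and 3, and 37 and 40 without controls 6 and 8. Lists ranged from 4 (without replicate 1) to 8 in trisomy 13, from 1 (without replicate 2) to 6 in trisomy 16, from 2 to 5 for all trisomies (5 without trisomy 16 replicate 1 or 3, control 4 or trisomy 1) and from 4 (without trisomy 16 replicate 3) to 8 for the difference. Chromosome 13 genes away from 1.5-fold were 0 (without trisomy 13 replicate 3 or 4) to 8 (without replicate 1), with 5 without replicate 2 and 6 without trisomy 16 replicate 1; those of chromosome 16 were 0 to 1 (without trisomy 16 replicate 3 or control 9). The correlation ran from -0.39 (without trisomy 16 replicate 1) to 0.51. The mitosis and replication lists of trisomy 16 ran from -0.072 and -0.067 (without its replicate 2) to 0.87 and 0.72 (without its replicate 3).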

Other observations

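The counts and values in this part were computed after the data were seen and are given without an explanation. Mdk was between 3.50 and 5.45 in the 4 trisomy 13 lines, but 10.75 in trisomy 1 and 10.52 in trisomy 19, above the control mean of 9.05. Sncg was at 6.26 in trisomy 1 and between 4.89 and 5.63 in trisomy 13, against at most 3.84 in the controls. It is the only gene past the threshold in both trisomy 1 and trisomy 13, and 0 genes were shared by either with trisomy 16. Slc7a3 was between 6.69 and 7.94 in trisomy 13 and at 7.99 in trisomy 1, with a control minimum of 8.82.

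The single trisomy 1 array had interferon response genes at a median of -0.49 (percentile 0.385) and cholesterol synthesis genes at 0.32 (percentile 99.7). In trisomy 19, imprinted genes had a median of 0.40 and matrix genes one of 0.18, both at percentile 100, glycolysis genes -0.34 (percentile 0.020) and smooth muscle markers -0.34 (percentile 0.090), all 10 of the latter below the control mean.

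On each extra chromosome the median change was smaller for genes with a mean log2 above 12 than for genes between 6 and 8. Without the 3'-biased arrays it was 0.47 against 0.95 in trisomy 1 and 0.50 against 0.76 in trisomy 13. It was 0.42 against 0.72 in trisomy 16 and 0.45 against 0.74 in trisomy 19. Genes between 4 and 6 had medians of 0.76, 0.50, 0.52 and 0.74 in the same order. The change thus did not fall steadily with the level. On the 3'-biased arrays chromosome 19, which has its normal copy number there, was at -0.40, -0.38 and -0.58.

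Of the 6 unbiased trisomic arrays, 5 correlated best with an array of the same first number and 1 with an array of the same group. Of the 9 controls, 7 correlated best with an array of the same number, and each of the 3'-biased arrays correlated best with another of these. Y-linked genes were above 5 in 4 of 9 controls, 3 of 4 trisomy 13, 2 of 3 trisomy 16 and 1 of 1 trisomy 1 arrays, and in 0 of 1 trisomy 19 array, so the lines are of mixed sex.

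Macrophage markers stood out on 2 arrays. On trisomy 13 replicate 4, Cd53 was at 7.18, Tyrobp at 6.17 and Ptprc at 5.66, besides Ctss, Lyz2 and Laptm5 given above; on control replicate 8 these 3 were at 4.80, 4.94 and 2.02. Over the 17 markers the mean was 3.40 in trisomy 13 and 2.88 in controls. Whether other cells in this culture contribute to the changes of trisomy 13 was not tested; its count of genes was 26 without replicate 4 and 63 without control replicate 8.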
